A study of Mus musculus with 4 samples.

How the data were processed

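Total RNA of tibialis anterior muscle was measured on 4 Affymetrix Mouse Genome 430 2.0 arrays, 1 for each of 4 groups: mdx and mdx/MMP-2 null mice at 1 and at 3 months. Groups were taken from the sample labels. Per the labels, RNA was isolated on RNeasy columns and labelled with biotin after 1 cycle of cDNA synthesis. The values are intensity, deposited by the authors as MAS5 summaries per probe set on a linear scale and made in Affymetrix Expression Console per the submitters' processing notes. Versions and scaling settings of these tools were not given in the sources used here. The deposited intensity columns were not scaled to a common target: their 2% trimmed means stood at 0.99 (mdx, 3 months), 1.07 (mdx/MMP-2 null, 1 month) and 1.34 (mdx/MMP-2 null, 3 months) relative to mdx at 1 month.

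The comparisons, the main floor, the gene rule, the size threshold, the additive model, the gene lists, the rule for named genes and the alternatives other than those marked as added were fixed before the data were examined. The plan had assumed signals scaled by MAS5. Because this did not hold, quantile normalization, which the plan had listed as a second choice, became the main scaling before any difference between groups was counted, and the deposited signals without scaling became a further choice.

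Of 45101 probe sets, 64 were Affymetrix controls. Of the other 45037, 34945 carried 1 gene symbol, 932 several and 9160 had no symbol here. Gene identifiers of 34741 single-gene probe sets matched the mouse gene table, which changed 0 symbols. This gave 18193 genes. No coordinates were given with the values, and none are printed. Arrays were quantile normalized in limma 3.58.1 under R 4.3.3. Signals below 17.4, the 50th percentile of all non-control signals over the 4 arrays, were raised to it, and values were put on the log2 scale. Each gene was represented by its single-gene probe set with the highest mean log2 signal. Genes at the floor in all 4 arrays were left out, which kept 12801 genes. A fold against an array at the floor is given as a lower bound, and none is given where both arrays were at the floor. Tables were made in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.

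The 4 differences were mdx/MMP-2 null minus mdx at 1 and at 3 months, and 3 months minus 1 month in each genotype. With 1 array per group they have no test, so genes at or past 2-fold were counted in each direction. Genes past 2-fold alike at both ages were set beside the count that independent lists would give. The additive model of genotype and age was fitted with lmFit and eBayes in limma over the 4 arrays, with 1 residual degree of freedom per gene and Benjamini-Hochberg adjustment over 12801 genes. Counts adjusted over the list alone came from the same fit and were added after the differences had been seen. They were run under the main setting only and were not corrected over lists.

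There were 35 fixed lists: 21 biological groups (metalloproteinases and inhibitors, angiogenic factors, interstitial matrix, TGF-beta signalling, basement membrane, dystrophin-associated complex, myogenic regeneration, IGF signalling, atrophy, slow fibre, fast fibre, cell cycle, chemokines and cytokines, interferon response, antigen presentation and complement, oxidative phosphorylation, glycolysis, fatty acid handling, circadian clock, immediate early and heat shock, sex chromosomes) and 14 sets of cell type markers. For each list the median log2 difference, relative to the median of all genes, was placed among 10000 random lists of equal size, drawn with replacement from 20 bins of mean expression. A list was said to lie outside the random range at or below the 2.5 or at or above the 97.5 percentile. Lists with fewer than 3 measured genes got no median. These percentiles describe single arrays and carry no p-value.

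Genes were named by a rule: Mmp2 and Dmd, the 10 genes with the largest genotype difference and the 6 with the largest age difference in each direction whose higher signal was at or above 85.4 (the 75th percentile), genes past 2-fold alike at both ages, genes called in the additive fit, up to 4 members of a list with the largest differences, and 7 angiogenic genes whatever their values. Predicted and unnamed genes were passed over. Genes named in the counts adjusted over the list alone, the sex-linked genes printed with signals, and the genes named in the closing paragraphs were chosen after their values were seen.

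The analyses were repeated with median scaling, cyclic loess scaling, floors at the 60th and 40th percentile, no floor with a pseudocount of 4.36, the mean of all probe sets of a gene, leaving out probe sets prone to cross-hybridise (_x_at and _s_at), a 3-fold threshold, a variance prior that follows signal, unadjusted p, and random lists not matched on expression. These had been listed beforehand. Analyses with no scaling, and with only genes at or above the 75th percentile counted, were added after the data were seen.

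The pipeline was tested on simulated data with the design and gene number (12801) of the genotype effect over both ages. Planted genes of all sizes were simulated together, which eases the adjusted threshold, and were drawn from genes of higher signal. The additive fit called 2 of 50 genes planted at 2-fold, 45 of 50 at 4-fold, 49 of 50 at 8-fold and 50 of 50 at 16-fold, with 12 false calls, and 256 unchanged genes passed 2-fold at 1 month and 250 at 3 months. The simulated spread came from the additive fit, whose residual holds any genotype difference that was unlike at both ages. The counts of unchanged genes are therefore no measure of how many genes would pass 2-fold without an effect. The call rates do not carry over to the data either. There Mmp2, 39.9-fold lower at 1 month and 19.7-fold lower at 3 months, was not called in the main setting. The 0 calls for genotype thus do not exclude large differences. For the genotype difference at 1 month, lists of 20 genes shifted by 0.3 on the log2 scale lay outside the random range in 20 of 20 trials. Unshifted lists did so in 0 of 20. These lists were random genes, so the trials do not cover lists whose genes vary together. Smaller shifts were not tried, and at 1 month only the interferon median outside the range was larger than 0.3. Probe sets with several or no gene symbols entered no gene count, list or additive fit. They appear only in the closing sections, where those of globin and immunoglobulin genes were compared between arrays. The test on cartilage or bone tissue replaced an earlier form, set before its outcome was seen, which asked whether over 50% of the further genes were highest in the mdx array at 1 month (9 of 11 were). That form counted Acan, a member of a fixed list, and took no account of the lower signals of these genes at 3 months.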

Results

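Expression was measured in tibialis anterior, a fast muscle of the lower leg, with 4 Affymetrix Mouse Genome 430 2.0 arrays. The mice were mdx, which lack dystrophin and are a standard model of Duchenne muscular dystrophy, or mdx that also lacked matrix metalloproteinase 2 (MMP-2), here called mdx/MMP-2 null. MMP-2 is a secreted gelatinase that degrades basement membrane and denatured collagen. Each genotype was sampled at 1 month, a period of active necrosis and regeneration in mdx muscle, and at 3 months. There was 1 array per group, so no group had replicates and the number of arrays limits the precision. None of the 4 differences between arrays was tested, and "higher" and "lower" describe those arrays. The sources used here do not say whether RNA of several animals was pooled.

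The deposited signals had 2% trimmed means of 92.1 for mdx and 98.3 for mdx/MMP-2 null at 1 month, and of 91.2 and 123.5 at 3 months. After quantile scaling, 12801 genes exceeded the signal floor of 17.4 in at least 1 array. Across these genes, the arrays of both genotypes correlated with Pearson r = 0.988 at 1 month and 0.985 at 3 months, and the arrays of both ages with r = 0.98 in mdx and 0.979 in mdx/MMP-2 null, where genes are not independent replicates. The 3'/5' signal ratio of Actb, a measure of RNA integrity and labelling, was 1.19 in mdx and 1.05 in mdx/MMP-2 null at 1 month, and 2.36 and 2.09 at 3 months. That of Gapdh lay between 0.85 and 0.94. Of 136 medians of fixed gene lists (34 lists, 4 differences), 59 lay outside the central 95% of random lists. By chance 6.8 would if the genes within a list varied independently. Random lists were drawn without regard to function, so a shift shared by the genes of a cell type can place its list outside. The excess over 6.8 is therefore no measure of an effect of genotype or age. The lists and differences are not independent either.

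The difference at 1 month addressed what loss of MMP-2 alters in regenerating dystrophic muscle. Mmp2 itself was 39.9-fold lower in the mdx/MMP-2 null array, with scaled signals of 24.7 against 985. Its other probe set gave 20.8 against 974. Of the other genes with large differences, Col2a1, the main collagen of cartilage, was 5.83-fold lower (29.8 against 174), Ibsp, a bone sialoprotein, at least 6.22-fold lower (15.8 against 109), and Mmp13, a collagenase of cartilage and bone, 3.0-fold lower (54.1 against 163). The mdx array at 1 month held the highest signal of the 4 arrays for all 3 genes. Socs3, a feedback inhibitor of cytokine signalling, was 5.74-fold lower (114 against 651), and Myh7, the slow myosin heavy chain, was 2.58-fold higher (409 against 159).

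The remaining genes with the largest differences at 1 month were of mixed function. Fos, an immediate early transcription factor, was 2.4-fold lower (190 against 456). Ndrg4 was 2.61-fold, Ano1 2.55-fold, Lsm7, a component of RNA processing complexes, 2.54-fold and Klk1, tissue kallikrein, 2.32-fold lower. Wdr70 was 3.14-fold higher (197 against 62.8), and Angptl4, an inhibitor of lipoprotein lipase, was 2.52-fold higher (323 against 128). Mss51, Inpp5j, Slc30a3, Mirg, Dnajb12, Nxph3 and Tcf20 were higher by 2.18-fold to 2.46-fold. For Dnajb12 another probe set lay the opposite way. The dystrophin gene Dmd, which still gives transcripts in mdx mice, had signals of 124 in mdx/MMP-2 null and 123 in mdx, and its other probe sets above the floor lay on both sides (48.2 against 36.7, and 24.0 against 28.8).

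By list, interferon response genes stood furthest above 0 at 1 month: 17 of 20 were higher in mdx/MMP-2 null, with a median log2 difference of 0.32, against -0.14 to 0.12 for the central 95% of random lists. Rsad2, an antiviral enzyme, was 2.08-fold, Zbp1 1.85-fold, Ifit3 1.84-fold and Oasl2 1.65-fold higher. Endothelial markers had a median of 0.15, with 13 of 19 higher, and atrophy genes a median of 0.1, with 16 of 20 higher. Cldn5, an endothelial tight junction protein, was 1.35-fold higher and Pdk4, which restrains pyruvate oxidation, 1.8-fold higher. Tendon and cartilage markers had a median of -0.24, with 10 of 14 lower. Col11a1, a further cartilage collagen, was 1.85-fold lower, and Acan, the cartilage proteoglycan aggrecan, at least 2.01-fold lower. Immediate early and heat shock genes had a median of -0.12 (20 of 29 lower, among them Myc, 2.04-fold lower, and Junb, 1.83-fold lower), antigen presentation and complement -0.13, and macrophage and monocyte markers -0.09.

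The other lists lay within the range of random lists at 1 month. The metalloproteinase and inhibitor median was -0.1, that of angiogenic factors and receptors -0.06, fibrillar collagens and interstitial matrix -0.06, TGF-beta and fibrosis signalling -0.02, basement membrane -0.07, the dystrophin-associated complex 0.0, myogenic regeneration 0.01, and muscle growth and IGF signalling 0.01. The slow fibre median was 0.08, fast fibre -0.01, cell cycle -0.1, chemokines and cytokines -0.08, oxidative phosphorylation 0.02, glycolysis 0.02, fatty acid handling 0.05, and circadian clock outputs 0.06. The 4 measured sex chromosome genes had a median of 0.19, and the marker medians of the remaining cell types ranged from -0.24 (T and NK cells, 5 genes measured) to 0.15 (Schwann cells and nerve). Of the angiogenic genes fixed for naming, the growth factor Vegfa had a log2 difference of -0.15, its receptors Kdr and Flt1 0.15 and -0.27, the nitric oxide synthases Nos3 and Nos1 -0.05 and -0.27, Hif1a -0.18 and the endothelial adhesion molecule Pecam1 -0.02. For Vegfa, Flt1 and Nos1 at least 1 other probe set lay the opposite way.

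In all, 73 genes were at least 2-fold higher and 74 at least 2-fold lower in mdx/MMP-2 null at 1 month, 1.15% of the genes. With the deposited signals left unscaled, which moved the median of all genes by 0.09 on the log2 scale, the counts were 131 and 35.

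The difference at 3 months addressed what loss of MMP-2 alters once the first wave of regeneration has passed. Mmp2 was 19.7-fold lower (40.9 against 805). Genes of myeloid inflammatory cells were higher. S100a9 and S100a8, calcium-binding proteins abundant in neutrophils, were 10.7-fold (216 against 20.2) and 9.56-fold higher (343 against 35.9), and Chil3, a chitinase-like protein of macrophages, at least 10.7-fold higher (187 against 16.9). All 26 measured macrophage and monocyte markers were higher in mdx/MMP-2 null, with a median log2 difference of 0.57 against -0.12 to 0.1 for random lists, and the 8 neutrophil markers had a median of 1.11. Fibrillar collagen and matrix genes were higher in 27 of 32 cases, with a median of 0.3.

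Among chemokines and cytokines, 19 of 22 were higher, with a median of 0.61. Ccl7 and Ccl2, chemokines that draw monocytes, were 4.75-fold (111 against 23.4) and 3.08-fold higher (176 against 57.1), Cxcl5, which draws neutrophils, at least 4.37-fold higher and Ccl9 2.48-fold higher. Of the macrophage and monocyte markers, the chemokine receptor Ccr2 was 2.29-fold, the scavenger receptor Msr1 2.23-fold, Fcer1g 2.01-fold and the mannose receptor Mrc1 1.93-fold higher. Of the neutrophil markers, Csf3r was at least 3.0-fold and Ngp 2.52-fold higher. Ccr1, a receptor for inflammatory chemokines, was 4.33-fold higher (204 against 47.0), Ptpn6, a phosphatase of blood cells, 4.06-fold (153 against 37.6), Slfn4 at least 5.91-fold (103 against 17.0) and Hp, haptoglobin, 2.97-fold (171 against 57.5).

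Matrix and protease genes formed a further group at 3 months. Timp1, an inhibitor of metalloproteinases, was 3.57-fold higher (1018 against 285), Mmp3, stromelysin, 2.88-fold higher (356 against 124) and the aggrecanase Adamts4 at least 2.87-fold higher, although another probe set of Adamts4 lay the opposite way. The metalloproteinase list as a whole had a median of 0.08, within the random range. Lox, which cross-links collagen, was 2.12-fold, the proteoglycan Bgn 2.05-fold and Ccn2, connective tissue growth factor, 1.94-fold higher. TGF-beta and fibrosis signalling had a median of 0.15, with Ltbp2 2.19-fold and Tgfbi 1.91-fold higher, and fibroblast markers a median of 0.21, with 14 of 15 higher.

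Muscle genes differed at 3 months as well. Slow and oxidative fibre genes had a median of 0.43, with 12 of 15 higher: Myh7 was 1.96-fold (602 against 307), Tnnc1 and Tnnt1, subunits of slow troponin, 1.95-fold and 1.79-fold, and Myl2, slow myosin light chain, 1.71-fold higher. Fast fibre genes had a median of -0.03. Many of these lay near the top of the array's signal range, such as Actn3 at 11493 and 12362. Myogenic regeneration genes had a median of 0.17, with 18 of 33 higher, among them Gadd45a, 1.97-fold, and Myh3, embryonic myosin, 1.55-fold. Dlk1 of that list was at least 2.04-fold lower. Satellite cell markers had a median of 0.27, with 10 of 12 higher, cell cycle genes 0.24, with 24 of 31 higher, and atrophy genes 0.17, with the metallothioneins Mt1 and Mt2 2.91-fold and 2.82-fold higher and the ubiquitin ligase Fbxo32 1.77-fold lower, with another probe set the opposite way.

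Endothelial markers were lower at 3 months, with a median of -0.2 and 15 of 19 lower, among them Icam2, 1.66-fold, and Cldn5, 1.4-fold. With unscaled signals their median was 0.27, against 0.41 for all genes, and that of the sex chromosome genes 0.09. Cd34 of that list was 1.35-fold higher. Angiogenic factors and receptors had a median of -0.06, within the random range. Vegfa had a log2 difference of -0.51 (184 against 262), Kdr -0.2, Flt1 -0.33, Nos3 0.24, Nos1 -0.38, Hif1a 0.27 and Pecam1 -0.24. The other Vegfa probe set hardly differed (39.0 against 39.3), and another probe set of Flt1 lay the opposite way. Angpt2, a ligand of the endothelial receptor Tek, was 1.91-fold lower. Adipocyte markers had a median of 0.34, antigen presentation and complement 0.13, immediate early and heat shock genes 0.14, and the 4 measured sex chromosome genes -0.34, with no member at or past 2-fold. Medians of the basement membrane list (0.02), the dystrophin-associated complex (-0.1), IGF signalling (-0.04), interferon response (0.08), oxidative phosphorylation (-0.1), glycolysis (-0.05), fatty acid handling (-0.01) and clock outputs (-0.08) lay within the random range, as did pericyte (0.0), T and NK cell (-0.09), B cell (0.1), eosinophil and mast cell (-0.14), Schwann cell (0.11), tendon and cartilage (0.0) and skin markers (-0.12).

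The genes most lower at 3 months besides Mmp2 were Sco2, a copper chaperone of cytochrome oxidase (at least 5.9-fold, 16.4 against 103), Nr4a3, an orphan nuclear receptor (3.35-fold, 101 against 337), Lsm7 (2.73-fold), Zfp788, Snai3, Galm, Pkn3, Tnrc6b and G0s2, an inhibitor of lipolysis (2.01-fold to 2.29-fold). Other probe sets of Galm and Tnrc6b lay the opposite way. Dmd was 1.35-fold lower (113 against 154), but another of its probe sets was higher (25.5 against 22.3). In all, 151 genes were at least 2-fold higher and 54 at least 2-fold lower, 1.6% of the genes. With unscaled signals, which moved the median of all genes by 0.41, the counts were 855 and 13.

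**Figure D1:**
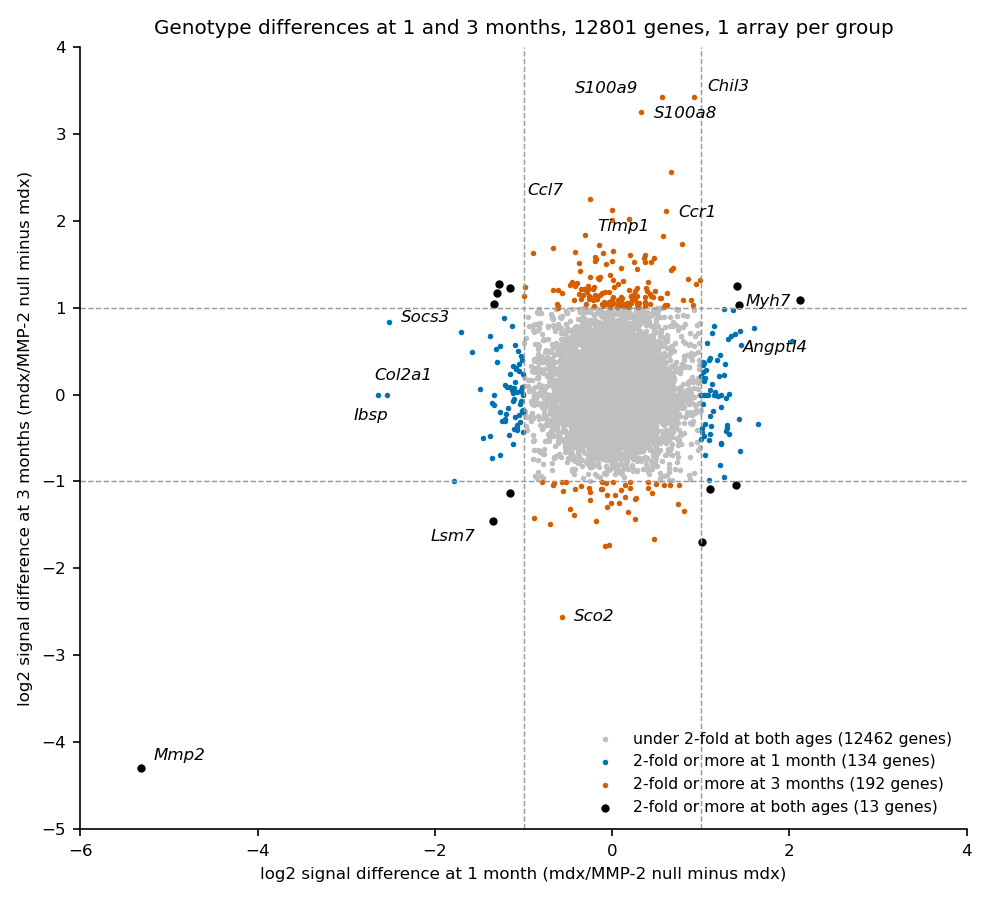
Each point is a gene placed by its log2 signal difference (mdx/MMP-2 null minus mdx) at 1 month on the horizontal axis and at 3 months on the vertical axis, with dashed lines at 2-fold. Mmp2 is far from all other genes at the lower left, and S100a9, S100a8 and Chil3 lie at the top, past 2-fold at 3 months alone.

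The differences at both ages were set side by side to ask which genes differed between genotypes alike. Lsm7 was lower in mdx/MMP-2 null at 1 month (183 against 464) and at 3 months (145 against 397). Besides Mmp2 and Lsm7, Vars2, a mitochondrial valyl-tRNA synthetase, was at least 2-fold lower at both ages (2.23-fold and 2.18-fold), but its other probe set lay the opposite way at 3 months and the mean of its probe sets gave a log2 difference of 0.07. Sncb, beta-synuclein, was 2.66-fold and 2.37-fold higher, Atp4b, a subunit of the gastric proton pump, at least 2.69-fold and 2.04-fold higher, and Krtap12-1, a keratin-associated protein, at least 4.35-fold and at least 2.13-fold higher, with a signal of at most 76.0 in any array for these 3 genes. Slow myosin Myh7 was 2.58-fold and 1.96-fold higher and its light chain Myl2 1.75-fold and 1.71-fold higher.

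These were 3 genes higher and 3 lower at both ages, where independent lists would share 0.86 and 0.31. The 3 lower genes include Mmp2, whose loss defines the genotype. A further 7 genes passed 2-fold in opposite directions, where 1.18 would be shared. Genes unlike in direction thus exceeded the count for independent lists too, so these counts do not show agreement between the ages. Across genes, which are not independent replicates, the genotype differences at both ages had r = 0.02 and rho = 0.0. The genotype difference was higher at 3 months than at 1 month by 2-fold or more for 372 genes and lower for 216. With unscaled signals these counts were 941 and 103.

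**Figure D2:**
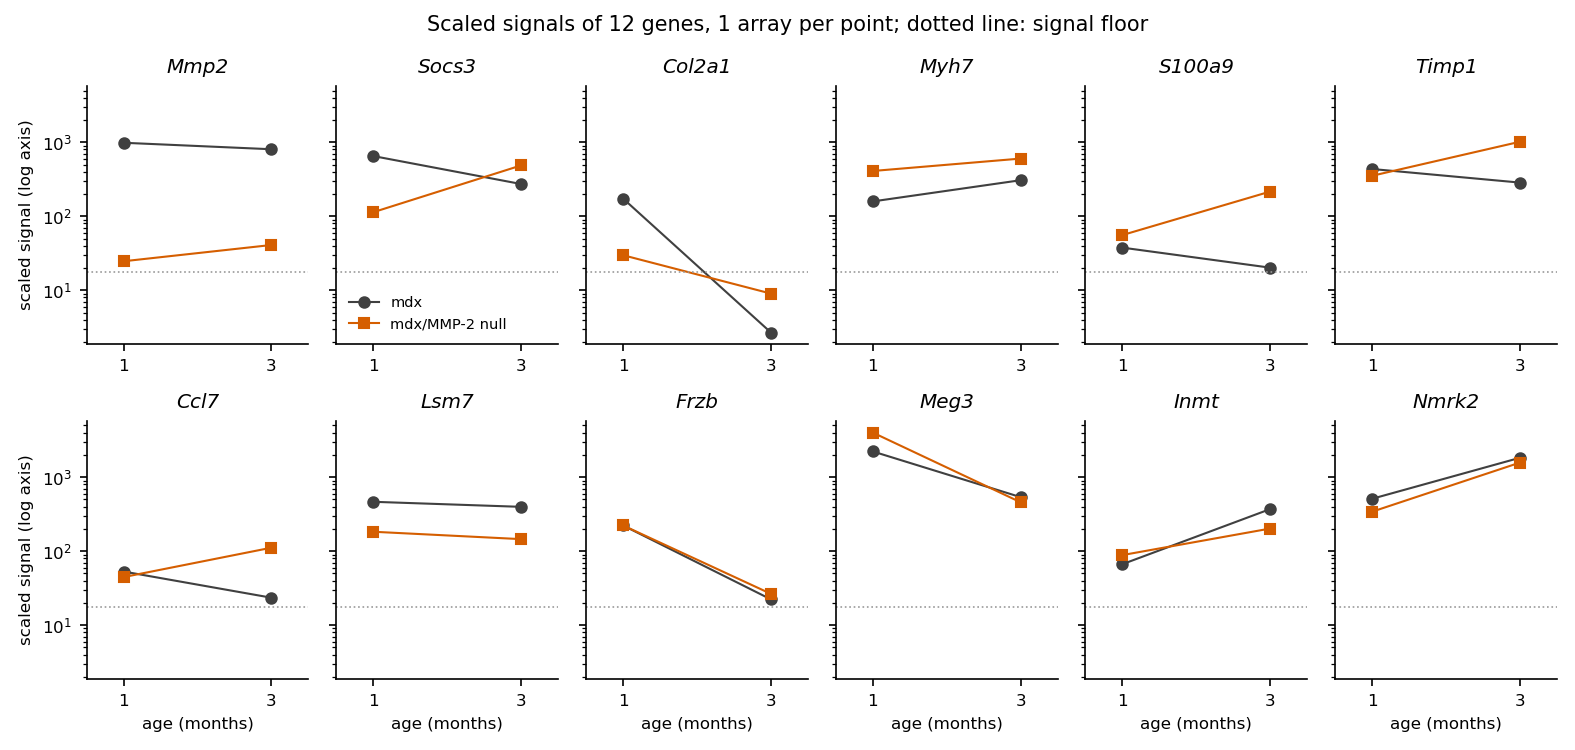
Quantile-scaled signals of 12 named genes on a log axis against age in months, with 1 array per point, mdx in grey circles and mdx/MMP-2 null in orange squares, and the signal floor dotted. Mmp2 and Lsm7 are lower in mdx/MMP-2 null at both ages, S100a9, Timp1 and Ccl7 are higher at 3 months, and Frzb and Meg3 are lower at 3 months than at 1 month in both genotypes.

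Age differences in mdx addressed how dystrophic muscle with MMP-2 alters between active regeneration and 3 months. The series holds no array of wild-type muscle, so in either genotype normal growth cannot be told apart from a change in regeneration. Myogenic regeneration genes were lower at 3 months in 28 of 33 cases, with a median log2 difference of -0.66. Myh3 was 3.41-fold (479 against 1630), Dlk1, an imprinted regulator of growth, 3.44-fold, Cdkn1c, an imprinted cell cycle inhibitor, 3.39-fold and Tnnt2, the troponin T of developing muscle, 2.84-fold lower. Matrix genes were lower in 29 of 32 cases (median -0.64), and all 19 basement membrane genes were lower (median -0.59). Col1a1, the main collagen of fibrous tissue, was 2.37-fold lower (1823 against 4327), and the heparan sulfate proteoglycan Agrn 3.11-fold lower. The Actb 3'/5' ratio was higher in the 3-month array, 2.36 against 1.19.

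Largest among the genes lower at 3 months in mdx were Frzb, a secreted Wnt antagonist (9.98-fold, 22.3 against 222), Col2a1 (at least 9.96-fold), Mmp13 (7.32-fold), Ibsp (at least 6.22-fold), the imprinted non-coding RNA Rian (4.71-fold, 229 against 1079) and the potassium channel subunit Kcne1l (4.52-fold). Higher at 3 months were Inmt, a methyltransferase (5.56-fold, 370 against 66.6), Cdkn2a, which encodes cell cycle inhibitors and marks senescent cells (at least 5.03-fold), Mss51, a muscle gene (4.46-fold), Rasd2 (4.25-fold), Pfkfb3, a stimulator of glycolysis (3.71-fold), and Galm (3.69-fold). Atrophy genes had a median of 0.13, within the random range, with Fbxo32 3.13-fold higher. Circadian clock outputs had a median of 0.21 (14 of 18 higher), with Ciart 3.01-fold and Nr1d1, a repressor of the clock, 2.21-fold higher.

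Other lists below the random range in mdx were cell cycle (median -0.53, with Top2a 2.61-fold and Mki67 2.23-fold lower), fibroblast (-0.5), tendon and cartilage (-0.48), neutrophil (-0.41), endothelial (-0.37, with Pecam1 2.26-fold lower), satellite cell (-0.36, with Pax7 2.15-fold lower), macrophage and monocyte (-0.32), IGF signalling (-0.24, with Igf2 2.42-fold and Igf1 1.8-fold lower) and angiogenic factors (-0.17). In that last list, Vegfa had a log2 difference of -0.49, Kdr -0.58, Flt1 0.51, Nos3 -0.72, Nos1 0.55 and Hif1a -0.08. Another probe set lay the opposite way for Vegfa (39.3 against 38.0), Nos1 (230 against 237), Flt1, Igf2 and Top2a. The 4 sex chromosome genes had a median of 0.36, above the range. Of these, Xist lay near the floor (23.0 against 16.9), and another probe set of Uty lay the opposite way (11.9 against 24.0). Medians of the remaining lists with a value lay within it, between -0.3 (Schwann cells) and 0.3 (T and NK cells). In all, 125 genes were at least 2-fold higher and 198 lower at 3 months, 2.52% of the genes. With unscaled signals, which moved the median of all genes by -0.02, the counts were 67 and 253.

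Age differences in mdx/MMP-2 null addressed the same interval without MMP-2. Myogenic regeneration genes again had a median below 0 (-0.4), with 20 of 33 lower and 12 higher. Dlk1 was at least 9.86-fold (13.4 against 172), Cdkn1c 5.57-fold, Igf2, a fetal growth factor, 3.74-fold and Mest 3.49-fold lower at 3 months. These named genes are all imprinted. Basement membrane genes had a median of -0.58 (17 of 19 lower), with Agrn 2.26-fold and the collagen IV chain Col4a2 2.14-fold lower. Endothelial markers were lower in 18 of 19 cases (median -0.63), with Pecam1 2.64-fold and the receptor Tek 2.19-fold lower. Inflammatory genes were higher: chemokines and cytokines had a median of 0.54, macrophage and monocyte markers 0.33 (23 of 26 higher) and neutrophil markers 0.83. The Actb 3'/5' ratio was higher in the 3-month array, 2.09 against 1.05.

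Highest at 3 months relative to 1 month in mdx/MMP-2 null were Serpina3n, an acute-phase protease inhibitor (6.27-fold, 146 against 23.3), Chil3 (5.64-fold), Nmrk2, a kinase of NAD synthesis in muscle (4.61-fold, 1573 against 341), S100a8 (4.6-fold), Dnajc17 (4.47-fold, with another probe set the opposite way) and Socs3 (4.29-fold, 487 against 114). Lowest besides Dlk1 were the imprinted non-coding RNAs Meg3 (8.75-fold, 457 against 4001), Rian (8.06-fold) and Mirg (at least 7.41-fold), together with Frzb (8.4-fold) and Kcne1l (5.83-fold). Of the chemokines, Cxcl5 was at least 4.37-fold and Ccl2 3.38-fold higher. Of the proteases and inhibitors, whose median was 0.2, Mmp3 was 3.81-fold and Timp1 2.89-fold higher.

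Further lists above the random range in mdx/MMP-2 null were T and NK cells (0.83) and B and plasma cells (0.56), both with 5 genes measured, skin markers (0.46), atrophy genes (0.33), immediate early and heat shock genes (0.29, with Junb 3.16-fold higher) and antigen presentation and complement (0.22). Lists below it were Schwann cells (-0.43), matrix (-0.31, with Postn, periostin, 2.27-fold lower), tendon and cartilage (-0.28), IGF signalling (-0.27), interferon response (-0.25), fibroblast (-0.24), cell cycle (-0.17), fatty acid handling (-0.15) and angiogenic factors (-0.14). In that last list, Vegfa had a log2 difference of -0.85, Kdr -0.93, Flt1 0.45, Nos3 -0.43, Nos1 0.44 and Hif1a 0.37. The other Vegfa probe set hardly differed (39.0 against 39.4), and another probe set of Nos1 lay the opposite way (215 against 254). With unscaled signals, where the median of all genes was 0.26, the IGF signalling (0.03), fibroblast (0.11), cell cycle (0.04), fatty acid (0.24) and angiogenic (0.1) medians lay above 0. Medians of the remaining lists with a value lay within the range, between -0.2 (adipocytes) and 0.16 (clock outputs). In all, 188 genes were at least 2-fold higher and 156 lower at 3 months, 2.69% of the genes. With unscaled signals, which moved the median of all genes by 0.26, the counts were 466 and 92.

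**Figure D3:**
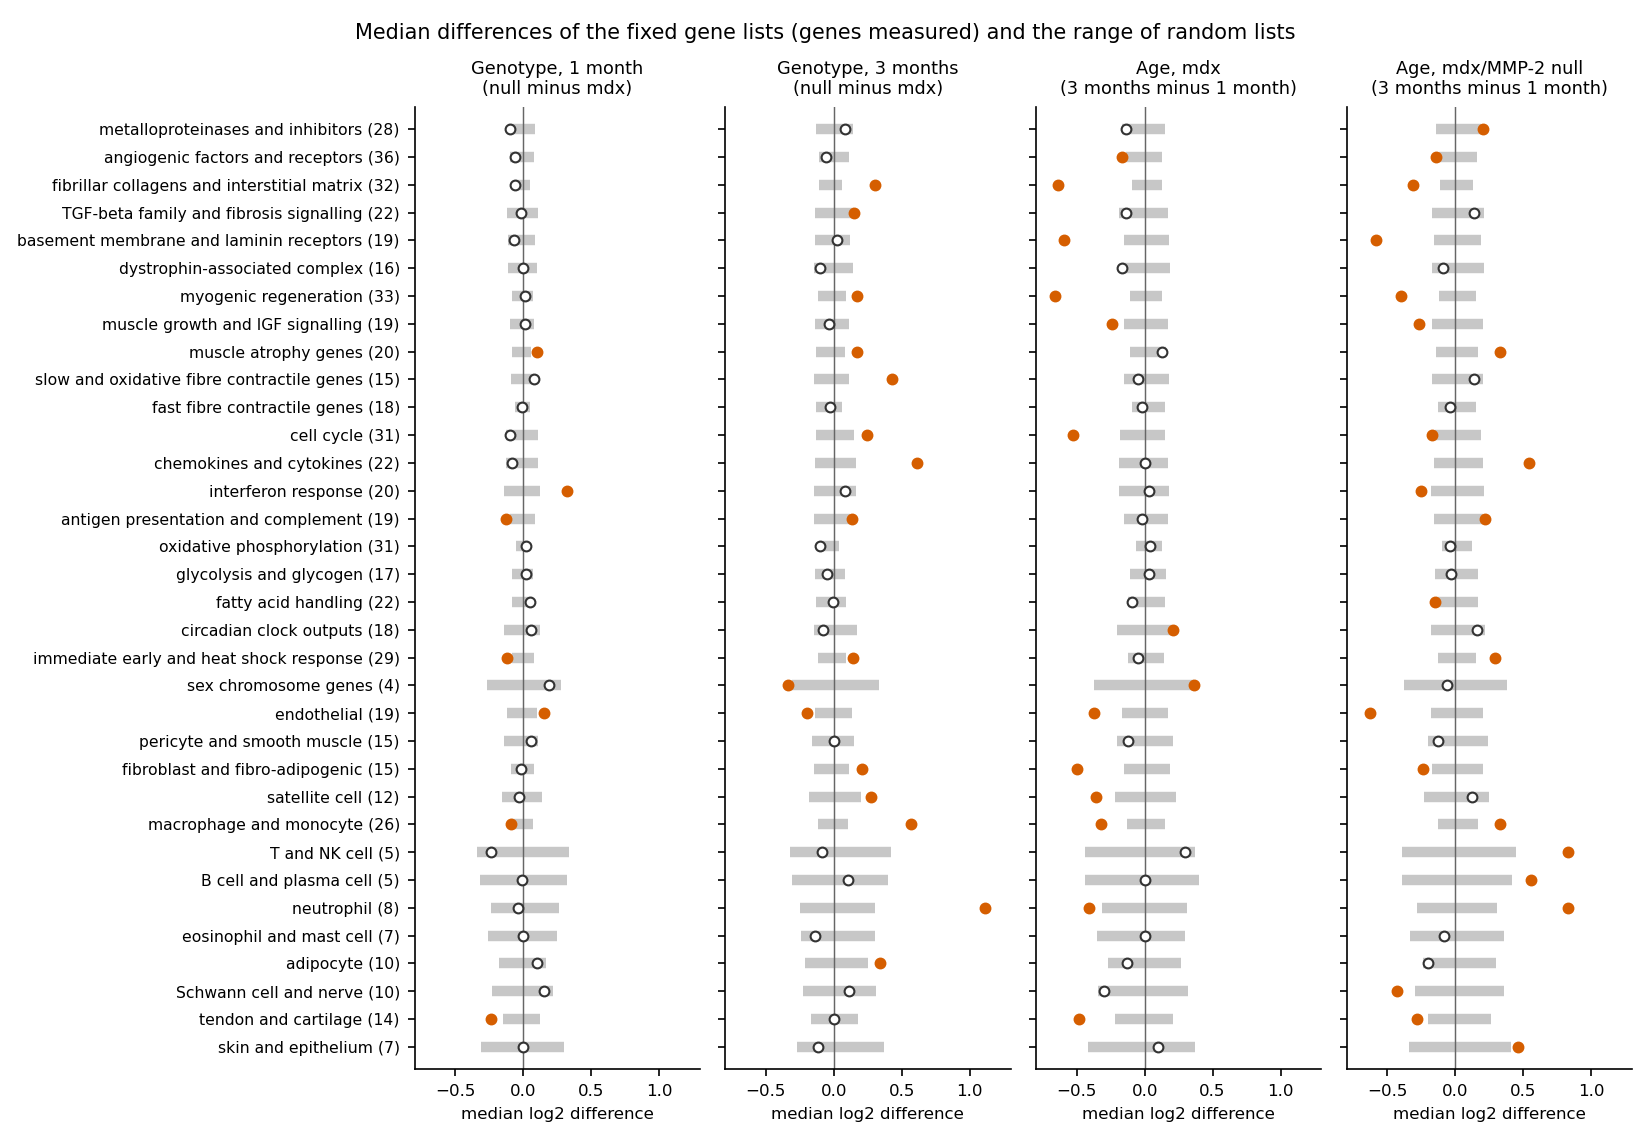
Median log2 differences of 34 fixed gene lists, with the number of genes measured, in 4 panels for the genotype differences at 1 and 3 months and the age differences in mdx and in mdx/MMP-2 null; grey bars span the central 95% of 10000 random lists, and orange points lie outside it. The neutrophil (1.11), chemokine (0.61) and macrophage (0.57) medians stand furthest above the range for genotype at 3 months.

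The age differences of both genotypes overlapped: 23 genes were at least 2-fold higher at 3 months in both and 43 lower in both, where independent lists would share 1.84 and 2.41, and 6 passed 2-fold in opposite directions. Frzb, Rian and Kcne1l were among those lower in both, and Cdkn2a was at least 5.03-fold and at least 4.41-fold higher. Across genes, the age differences of both genotypes had r = 0.35 and rho = 0.33. Both 3-month arrays also had higher Actb 3'/5' ratios (2.36 and 2.09) than both 1-month arrays (1.19 and 1.05), while Gapdh ratios lay between 0.85 and 0.94. RNA quality therefore cannot be told apart from age in this overlap, nor in the age effect of the additive fit.

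The test available was an additive limma fit of genotype and age to all 4 arrays, in which a difference unlike at both ages counts as spread. For genotype, limma called 0 genes at an adjusted p under 0.05, with 560 at an unadjusted p under 0.05. Mmp2 had the smallest adjusted p, 0.339, at a log2 difference of -4.81. For age, limma called 0 genes, with 1756 at an unadjusted p under 0.05. Frzb had the smallest adjusted p, 0.171, at -3.19. When the prior variance was allowed to follow signal, Mmp2 was lower at an adjusted p of 0.00304, and 52 genes rose and 78 fell with age. Over all settings the smallest adjusted p ranged from 1.28e-09 to 0.974 for genotype and from 6.2e-07 to 0.39 for age.

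Adjusted over the list alone, against 0 over all 12801 genes, limma gave more calls. With the 592 genes of all fixed lists together, Mmp2 fell in mdx/MMP-2 null (adjusted p = 0.0157) and 0 genes passed for age, with 148 at an unadjusted p under 0.05. Within single lists, not corrected for the number of lists, Myh7 and Myl2 of the slow fibre list rose in mdx/MMP-2 null at log2 differences of 1.17 and 0.79, Zbp1 of the interferon list rose at 0.99, and no other gene besides Mmp2 was called for genotype. For age, 13 of 19 basement membrane genes fell (Col4a2 at -1.11, Agrn at -1.41), as did 15 of 33 myogenic regeneration genes (Igf2 at -1.59, Cdkn1c at -2.12), while Ankrd1 and Xirp1 of that list rose. In addition, 7 of 32 matrix genes fell, among them Postn and Col1a1, with 6 of 31 cell cycle genes, 6 of 19 IGF signalling genes and 5 of 19 endothelial markers, among them Pecam1 at -1.29. The clock genes Ciart, Nr1d1 and Bhlhe40 rose, at 1.51, 0.99 and 0.74, where the hour of collection could not be told apart from age. In 2 lists 5 genes were called in mixed directions (fibroblast, tendon and cartilage), and each further list gave 3 calls or fewer.

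Of the sex-linked genes, Eif2s3y on the Y chromosome had signals of 480 to 638 over the 4 arrays, Kdm5d 63.2 to 107 and Xist, expressed from an inactive X chromosome, 14.3 to 23.0. Of the erythroid markers only Alas2 and Hbb-b2 could be measured, so the list has no median. Alas2 was 1.37-fold lower in mdx/MMP-2 null at 1 month and 1.4-fold lower at 3 months, and Hbb-b2 was 1.25-fold and 1.13-fold higher.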

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

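All tests here, on scaling, blood, a genotype difference at both ages, single arrays, dilution and cartilage or bone tissue, were chosen after the patterns they address were seen. Each difference between ages or genotypes given here was not itself tested, because each group had 1 array.

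Macrophage and monocyte markers had medians on opposite sides of 0 in the genotype difference, -0.09 at 1 month and 0.57 at 3 months. Their age medians did so too, -0.32 in mdx and 0.33 in mdx/MMP-2 null. Neutrophil markers had age medians of -0.41 in mdx and 0.83 in mdx/MMP-2 null. For each gene, genotype differences change between ages by as much as age differences change between genotypes. These reversals are therefore views of 1 pattern and not independent. Array scaling is argued against as the source of the 3-month difference, since the lowest macrophage median over 4 scalings, relative to all genes, was 0.51. A larger amount of blood is argued against too: globin probe sets differed by -0.09 to 0.37, with a mean of 0.08, against a neutrophil median of 1.11. Globin follows red cells, so more white cells in an equal amount of blood were not tested and stay open. With 1 array per group, the 1-month median of -0.09 leaves a genotype difference at both ages open, and a difference between the mice or dissections behind the arrays cannot be told apart from an effect of MMP-2. A hypothesis left open is that myeloid cells may be more abundant in 3-month muscle that lacks MMP-2.

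The 6 cartilage and bone genes picked after the values were seen (Col2a1, Ibsp, Mmp13, Col11a1, Col11a2 and Snorc) had a median genotype difference of -1.44 at 1 month, and all but Col11a2 (102 in mdx/MMP-2 null against 97.2) were highest in the mdx array at 1 month. Scaling is argued against, since the median relative to all genes was at most -1.39 under each of the 4 scalings (-1.3 itself with no scaling). Cartilage or bone tissue in that sample stays open: of 10 further genes of these tissues outside the fixed lists, 8 were highest in that array, at percentile 94.27 of random lists that were also lower with age in mdx, where the mean share was 56.1%. With Acan of the fixed lists added, the median of the 11 genes at 1 month was -0.21, at percentile 2.65 and so within the random range, and Matn4 and Ctsk were higher in mdx/MMP-2 null (42.6 against 40.4, and 364 against 317). An effect of genotype stays open as well, as it was not tested.

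Endothelial markers had a median of 0.15 for genotype at 1 month and -0.2 at 3 months. Dilution by RNA of other cells stays open: the endothelial median minus that of 40 other stromal markers pooled was -0.29, with a 95% bootstrap interval over genes of 1 pair of arrays of -0.41 to -0.14, and minus that of fibroblast markers -0.41 (-0.54 to -0.21), but the intervals against pericyte (-0.4 to 0.27) and Schwann cell markers (-0.44 to 0.04) reached past 0. Scaling stays open too, because the highest endothelial median over 4 scalings, relative to all genes, was -0.14, between the bounds set for it, and without scaling the median itself was 0.27 against 0.41 for all genes. A lower endothelial share of the tissue could account for it, and so could a difference between single samples.

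Other lists on opposite sides of 0 for genotype at 1 and 3 months were antigen presentation and complement, -0.13 and 0.13, and immediate early and heat shock response, -0.12 and 0.14. Single genes past 2-fold in opposite directions at 1 and 3 months were Fbxo36 (1.11 and -1.09), Galm (1.4 and -1.04), Marchf1 (-1.15 and 1.23), Serpina3n (-1.28 and 1.28), Snorc (-1.3 and 1.17), Spi1 (-1.34 and 1.04) and Zdhhc12 (1.01 and -1.69) on the log2 scale, mdx/MMP-2 null minus mdx. Probe sets with several or no gene symbols entered no gene count, list or additive fit. At 1 month, 947 of them had a signal at or above the 75th percentile. Of these, 12 were at least 2-fold higher and 4 lower in mdx/MMP-2 null. At 3 months, 10 of 938 were higher and 3 lower.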

How the results depend on the processing

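No scaling and the restriction to genes at or above the 75th percentile were chosen after the data were seen, and the other alternatives were planned. No paired analysis was possible because each group had 1 array and the labels pair no animals. Leaving out an array was not possible either, since it would remove a group and leave the additive model with no residual degrees of freedom. Signal over background limits what can be seen: genes near the floor of 17.4 give bounds. Of the 59 list medians outside the random range, 48 (mean of all probe sets) to 56 (cyclic loess, floor at the 40th percentile) stayed outside under each alternative, and 0 changed sign when taken relative to all genes. Without subtracting the median of all genes, 7 changed sign with no scaling, among them endothelial markers at 3 months (0.27), and 1 with median scaling (fatty acid handling with age in mdx/MMP-2 null, 0.07). The total outside the range was between 52 and 67 over the alternatives. Of 75 named differences past 2-fold, 75 stayed past it with median scaling, 74 with loess and 68 with the higher floor. The lower floor kept 75, the pseudocount 66 and the mean of all probe sets 58, and 65 of 69 stayed without _x_at and _s_at probe sets. With no scaling 72 stayed when taken relative to the median of all genes. No count without that subtraction is given for them. The exception in direction was Vars2 at 3 months, 0.07 with the mean of all probe sets. Median scaling, loess and leaving out _x_at and _s_at probe sets kept each count of genes past 2-fold within 1.5 times the main count. The other settings moved most of the counts that follow further than that. Not all moved so far, such as 253 against 198 genes lower with age in mdx with no scaling. Where a setting's own construction (a stricter threshold, floor or gene filter) does not show the cause, the cause was not tested.

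In the order of genotype at 1 month, genotype at 3 months, age in mdx and age in mdx/MMP-2 null, higher and lower genes numbered as follows, against 73 and 74, 151 and 54, 125 and 198, and 188 and 156 in the main setting. No scaling gave 131 and 35, 855 and 13, 67 and 253, and 466 and 92. The floor at the 60th percentile gave 30 and 29, 73 and 17, 67 and 123, and 107 and 104. The floor at the 40th percentile gave 172 and 148, 285 and 147, 235 and 348, and 299 and 261. The pseudocount gave 213 and 202, 347 and 182, 276 and 377, and 348 and 272. The mean of all probe sets gave 31 and 35, 81 and 28, 79 and 105, and 93 and 98. The 3-fold threshold gave 4 and 7, 20 and 6, 18 and 29, and 30 and 23. Genes at or above the 75th percentile gave 16 and 15, 53 and 10, 47 and 90, and 80 and 84.

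The genotype difference was higher at 3 months than at 1 month by 2-fold or more for 372 genes and lower for 216 in the main setting. The alternatives gave 941 and 103 with no scaling, 207 and 93 with the higher floor, 630 and 421 with the lower floor, 617 and 410 with the pseudocount, 203 and 112 with the mean of all probe sets, 67 and 37 at 3-fold, and 117 and 47 at or above the 75th percentile. Genes past 2-fold alike at both ages, 3 higher and 3 lower in the main setting, numbered 24 and 2 with no scaling, 0 and 2 with the higher floor, 7 and 6 with the lower floor, 37 and 24 with the pseudocount, 0 and 1 at 3-fold, and 0 and 2 at or above the 75th percentile.

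In limma, 0 genes passed for genotype or age in the main setting. For genotype, 1 gene was lower under the trended prior, median scaling and the higher floor each, 20 were higher and 1 lower with no scaling, and 323 were higher and 237 lower at an unadjusted p under 0.05. For age, 52 were higher and 78 lower under the trended prior, 1 lower under median scaling and under the higher floor, 39 higher and 40 lower with no scaling, and 853 higher and 903 lower at an unadjusted p under 0.05.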

Other observations

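Immunoglobulin transcripts were higher at 3 months than at 1 month in both genotypes. These 8 probe sets, of Igha, Ighm and Igkc, were picked after their values were seen, and 3 of them carry several gene symbols. All were higher at 3 months, 6 of them at least 2-fold in both genotypes, with median log2 differences of 1.92 in mdx and 2.2 in mdx/MMP-2 null. The fixed B cell and plasma cell list, with 5 genes measured, had a median of 0.0 in mdx, at percentile 50.08 of random lists. There 2 of its genes lay above 0 and 1 below, and Jchain was 2.89-fold higher (50.7 against 17.5). In mdx/MMP-2 null its median was 0.56, with all 5 genes above 0. Globin probe sets went the other way, with log2 differences between 1 and 3 months of -0.42 to -1.28 over both genotypes.

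Imprinted growth genes were lower at 3 months in both genotypes. The 9 measured genes that showed this (Igf2, Dlk1, Mest, Meg3, Rian, Mirg, Plagl1, Cdkn1c and Peg3) had median log2 differences of -1.76 in mdx and -2.48 in mdx/MMP-2 null. The list of further imprinted genes tested for the same drop was written after these were seen. Its 20 measured genes had medians of 0.1 in mdx, at percentile 89.39 of random lists, with 12 above 0, 7 below and 1 of these 2-fold lower, and -0.27 in mdx/MMP-2 null, at percentile 0.08, with 5 above 0, 13 below and none 2-fold lower. A drop shared by imprinted genes in general was not shown, and the hypothesis stays open.

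Genes next to a targeted locus can keep the sequence of the donor strain, so the passenger hypothesis was tested on the 100 measured genes nearest to Mmp2, 50 on each side in gene order. Their median absolute mean genotype difference was 0.152, against 0.13 for 222 other windows of equal size, at percentile 91.9, between the bounds set beforehand, so it stays open. Of these neighbours, Ndrg4 (-1.38 at 1 month and -0.48 at 3 months), Rtbdn (-0.88 and -1.42), Mt1 (0.0 and 1.54) and Mt2 (-0.07 and 1.5) passed 2-fold at either age. The part of Mmp2 that was removed is not given in the sources used here, so the place of the probe sets relative to it is unknown.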
